A study of Mus musculus with 7 samples.

How the data were processed

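The series measured cytosine methylation in E14 cells, a mouse embryonic stem cell line grown, per the labels' protocols, in serum with LIF and inhibitors of the MEK and GSK3 kinases. TAPS converts 5-methylcytosine and 5-hydroxymethylcytosine to a base read as T, so a modified CpG here stands for either mark. Per the labels' protocols, endonuclease enrichment TAPS (eeTAPS) converted genomic DNA, cut it at converted sites with the USER enzyme mix, kept fragments of 200 to 1000 bp and only then made the sequencing library. Per the labels' protocols, reduced representation TAPS (rrTAPS) cut DNA with MspI, ligated adapters, kept 100 to 400 bp fragments from a gel and only then converted them. The eeTAPS libraries started from 200 ng (2 replicates), 50 ng, 10 ng and 1 ng of DNA, and per the labels' protocols were amplified for 6, 8, 10 and 14 PCR cycles, so the number of cycles changed with the input and the effects of these cannot be separated. The rrTAPS library was amplified for 6 cycles. An eeTAPS control library of untreated DNA was not analysed here, so no background from unconverted DNA was measured.

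Reads were processed by the authors. Trim Galore, BWA 0.7.17-r1188, bedtools and the mm9 genome are named in the submitters' processing notes, with no role, order or settings given in the sources used here. Each of the 6 deposited files lists the same 21342779 CpGs. Per the file headers, the eeTAPS files give 3 count columns, named total, cleaved and uncleaved, followed by a fraction. Uncleaved reads are read here as modified but not cut at the CpG, because the deposited fraction equalled cleaved plus uncleaved reads over total reads, limited to 1, with a largest difference of 5e-07. Modified reads above the total occurred at 0.0343% to 0.0566% of the covered CpGs of an eeTAPS library and were limited to the total. The rrTAPS file gives, per the file headers, a count of modified reads, a count taken here as all reads, since the deposited fraction is their quotient, and that fraction, with no value at 13651094 CpGs and a total of 0 at a further 99001. Neither the labels nor the headers say whether positions count from 0 or from 1, so positions are printed as the files give them, in mm9. The coverage of a library, summed over CpGs, is not its number of reads, since a read can cover several CpGs.

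From the counts, a level was computed as modified counts over coverage, in percent. CpGs needed a coverage of 5. Levels of libraries and chromosomes were sums over sums, and levels of density classes were means over CpGs. Windows of 10 kb summed all their CpGs and needed a summed coverage of 50 in each library compared. Differences between a pair of libraries were unweighted means over the CpGs or windows that both measured. Intervals for the levels of single libraries or stretches are exact Clopper-Pearson 95% intervals; PCR reads without molecular identifiers are not independent molecules, so intervals cover counting error only. Intervals across CpGs treat CpGs as independent, which neighbouring CpGs are not. Local density was the number of other listed CpGs within 250 bp on each side. CpG-dense stretches were runs of at least 30 CpGs with gaps of at most 60 bp, found from positions alone, and a stretch was measured where at least 10 of its CpGs had a coverage of 5. Coverage relative to all CpGs counted no CpG for more than 500 reads.

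Groups were taken from the sample titles. Only the 200 ng group had replicates, and nothing in the labels says that these came from separate cultures, so their spread may be technical. The files of these 2 libraries differed in composition, with 26.0% and 11.0% of the coverage in the 1000 CpGs of highest coverage, and were counted as 2 samples. Pairs of libraries, with the 200 ng libraries pooled by adding their counts, were compared with Pearson's r across CpGs and windows and with a two-sided Fisher's exact test per CpG, called at an adjusted p below 0.05 and a difference of at least 20 percentage points. Such a test compares libraries, not conditions. CpGs are not independent replicates, and no p is attached to any r. Change with input was fitted with limma to the log2 odds of modified counts, with 0.5 added to both counts, in 10 kb windows with at least 3 CpGs of coverage 5 and a summed coverage of 50 in all 5 eeTAPS libraries, against log10 of the input as a line, at an adjusted p below 0.05. X was ranked among the 19 autosomes within each library. These designs, the alternatives to them and the rule for the regions named were fixed before the data were examined. The rule took the 5 longest stretches, taken as those with the most CpGs, at 50% or more in the pooled 200 ng libraries, and up to 5 rises and 5 falls, the largest, among windows that passed the test with input. Alternatives changed the coverage minimum, weighting, window size, chromosomes, density radius, stretch definition, thresholds, offset, limma's settings and the libraries used.

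Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used. The Fisher test was tested on simulated data, with 200 of 200000 CpGs changed by 80 percentage points at the real coverage. It recovered 49.5% of the changed CpGs for eeTAPS against rrTAPS, 27% for 1 ng against 200 ng and 31% for the 200 ng replicates, with 0 false calls in each. Of changed CpGs with 20 reads in both libraries it recovered 100% for eeTAPS against rrTAPS (21 CpGs) and for the replicates (16 CpGs), while the 1 ng simulation held none. The limma fit was tested on 20000 simulated windows, 200 of them with a slope of 1 or -1. It recovered 100% of these, with 25 false calls, or 11.1% of its calls, above the 5% intended. The spread between simulated libraries was a fixed setting, not estimated from the data. In the data, a window with a slope of 1.64 only just passed (limma adjusted p = 0.0415), so this recovery need not hold there. A fit with windows weighted by counting error, added afterwards, recovered 99.5% with 11 false calls, or 5.24%, but its weights assume the same spread that the simulation used. The unweighted fit was kept as designed.

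Promoter levels of gene lists, and the gene parts of the rule for names, were not run: the gene table given is of another build than mm9, and no genome was used here, so no gene was placed in the files' coordinates and no region is named by a gene. GC content was not examined for the same reason. A higher level of X, a higher unweighted mean level of the lower inputs at a coverage of 5 and the difference between the methods by CpG density were first weighed against technical explanations and then set aside; their values are given among the other observations.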

Results

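Methylation of CpGs was measured genome-wide in E14 mouse embryonic stem cells with eeTAPS, which reads fragments cut at modified CpGs, over an input series of 200, 50, 10 and 1 ng of DNA, and with rrTAPS, which reads the CpG-rich fragments left by MspI. The data comprised 2 eeTAPS libraries of 200 ng, 1 library each of 50, 10 and 1 ng, and 1 rrTAPS library, so that only the 200 ng group had replicates. Coverage summed over CpGs was 286122571 and 174586295 reads in 200 ng replicates 1 and 2, 66879583 at 50 ng, 48832215 at 10 ng, 35458359 at 1 ng and 101040325 for rrTAPS, each read counted at every CpG it covers. At least 1 read covered 95.2% and 90.9% of the listed CpGs in the 200 ng replicates, 76.6% at 50 ng, 68.7% at 10 ng, 56.8% at 1 ng and 35.6% for rrTAPS. A coverage of 5 was reached by 67.1%, 55.5%, 17.3%, 9.90%, 6.34% and 6.02% of CpGs in the same order. Mitochondrial CpGs had levels between 2.88% and 3.80% in the eeTAPS libraries and 0.334% in rrTAPS (95% interval 0.285 to 0.389%).

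The methylation level of the genome was compared among libraries. At CpGs with a coverage of 5, the 200 ng libraries had a level of 64.7% ± 2.57 (SD, n = 2), the 50 ng library 63.3%, the 10 ng library 61.4%, the 1 ng library 54.1% and the rrTAPS library 25.1%. The 50 ng library lay within the SD of the 200 ng replicates and the 10 and 1 ng libraries below both replicates (62.9% and 66.5%). Repeated sequence weighed on these sums. A single 10 kb window of chromosome 2 (98500000 to 98509999) held 29974327 of the coverage of 200 ng replicate 1, at a level of 39.9%. The adjoining windows of chromosome 9 that start at 3000000, 3010000 and 3020000 had levels of 40.8%, 39.9% and 34.3% in that library. The sum of the 1 ng library was also lowered by the chromosome 10 window from 62270000 to 62279999, described under other observations. It held 616302 of the 1 ng coverage, at a level of 2.44%. Chromosome 10 at 1 ng was at 29.9% by sums and at 71.7% by the unweighted mean. The coverage minimum also raised the unweighted level of a library with fewer reads. When 200 ng replicate 1 was thinned to the depths of the 50, 10 and 1 ng libraries, its unweighted mean level at that minimum, 65.8% at full depth, was 74.7%, 76.7% and 78.2%, against 74.7%, 76.0% and 71.1% in the libraries themselves. In a recalculation chosen after these values were seen, 18 windows with at least 100 times the median coverage of any eeTAPS library were left out. The level was then 70.9% ± 0.299 (SD, n = 2) at 200 ng, 75.9% at 50 ng, 76.6% at 10 ng and 71.1% at 1 ng, and the effect of depth on these values was not tested. CpGs of intermediate level made up 53.0% of the pooled 200 ng CpGs with a coverage of 10, against 39.7% at 80% or more and 7.25% at 20% or less. In 200 ng replicate 1 the order was the same but the shares were nearly equal, with 47.7% intermediate and 47.3% at 80% or more. In replicate 2 the class at 80% or more was the larger, at 54.7% against 40.0% intermediate. In rrTAPS the class at 20% or less was the largest, at 58.9%.

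Levels fell with each step of local CpG density in the eeTAPS libraries, and in rrTAPS from 5 to 9 neighbours on. In the 200 ng libraries, CpGs with 0 to 1 other CpGs within 250 bp had a mean level of 87.7% ± 0.713, those with 2 to 4 had 73.0% ± 0.564, those with 5 to 9 had 59.1% ± 1.92 and those with 10 to 19 had 43.8% ± 3.15 (SD, n = 2). The densest classes, which hold CpG islands, were at 17.5% ± 2.35 with 20 to 39 neighbours and at 4.40% ± 2.20 with 40 or more (SD, n = 2). Each step between classes exceeded the SD of the replicates. The 1 ng library fell from 86.1% in the sparsest to 4.85% in the densest class. In rrTAPS the sparsest class was at 49.0%, the next classes at 52.9% and 52.8%, and the densest at 0.616%. Coverage also followed density: 200 ng replicate 1 covered 71.2% of the sparsest but 10.1% of the densest class at 5 reads, whereas rrTAPS covered 0.164% and 47.4%.

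**Figure D1:**
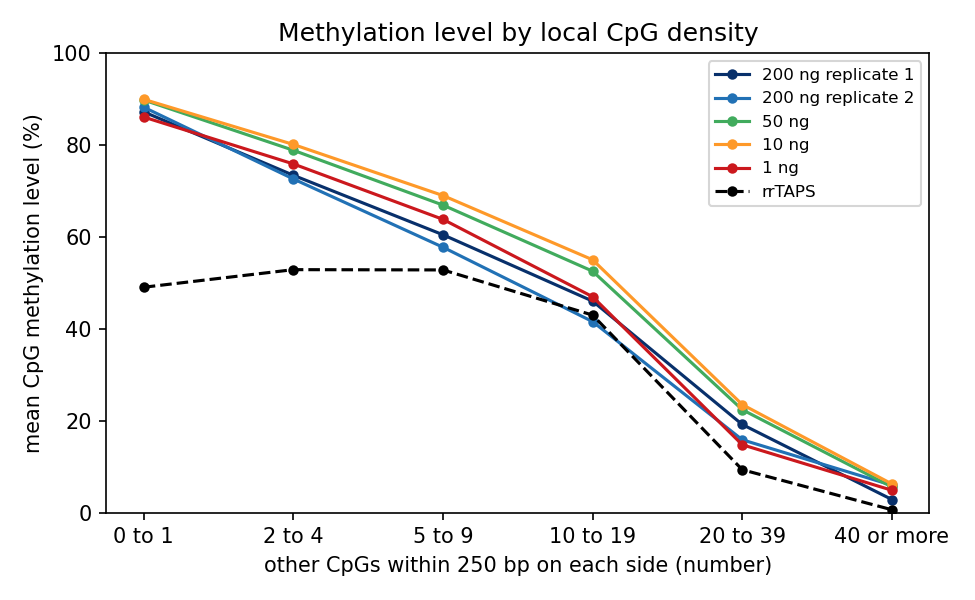
Mean methylation level in percent (vertical axis) of CpGs with a coverage of 5, by the number of other CpGs within 250 bp on each side (horizontal axis); each line with points is 1 library and the dashed line is rrTAPS. The eeTAPS libraries run from between 86.1% and 89.9% in the sparsest class to between 2.84% and 6.23% in the densest, and rrTAPS from 49.0% to 0.616%.

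The replicates of 200 ng were compared to set the background for other pairs. Across 10546785 CpGs their levels correlated with r = 0.731, and across 255430 windows of 10 kb with r = 0.910. At 317 CpGs, 0.00301% of those tested, the replicates differed by Fisher's exact test, with the level of replicate 1 higher at 282. At this depth the test recovered 31% of simulated changes of 80 points, so few calls do not show that the replicates were equal. On summed counts of 10 kb windows, with no minimum difference, 16760 of 255430 windows (6.56%) differed by Fisher's exact test at an adjusted p below 0.05. Replicate 1 was higher by 2.44 points on average over shared CpGs and by 0.473 points over windows. Of the CpGs called, 124 had more than 500 pooled reads.

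The input series addressed how far less DNA changes the measured levels. Over 10 kb windows the 1 ng library was lower than the pooled 200 ng libraries by a mean of 5.05 points (65.2% against 70.2%), with 76.3% of 219568 windows lower. The 50 and 10 ng libraries differed by -0.862 and -0.823 points. The replicates differed by 0.473 points over windows and by 2.44 points over single CpGs. Across single CpGs the mean differences from 200 ng were 0.318 points at 50 ng, 1.03 points at 10 ng and -2.98 points at 1 ng, with r of 0.737, 0.703 and 0.645. The differences at 50 and 10 ng were thus larger than that between the replicates over windows and smaller over single CpGs, and over single CpGs their sign changed at a coverage of 1, to -1.29 and -0.716. Over single CpGs they were 1.87 and 2.64 points without 200 ng replicate 1 and -0.409 and 0.240 without replicate 2. Fisher's exact test called 56 CpGs at 50 ng, 93 at 10 ng and 1973 at 1 ng, of which 1851 were lower at 1 ng. The 1 ng count was 271, with a mean difference of -1.46 points, without 200 ng replicate 1 and 977, with -3.62 points, without replicate 2. With 200 ng replicate 2 thinned to the depth of the 1 ng library and compared with replicate 1, a comparison added after the data were seen, r was 0.6996 and 0.00986% of CpGs were called, against 0.605 and 0.0755% for the 1 ng library itself. Thinned to the depths of 50 and 10 ng, replicate 2 gave more calls (0.00441% and 0.00598%) than those libraries did (0.00189% and 0.00473%). There was 1 library per lower input, so these differences have no replicate check.

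A fit across all 5 eeTAPS libraries asked which windows changed with input. Of 163262 windows, 14 rose with input and 0 fell by limma at an adjusted p below 0.05, and 30330 had an unadjusted p under 0.05. The largest rise was at chromosome 3, 133150000 to 133159999, with levels of 75.3% and 72.9% in the 200 ng replicates, 61.3% at 50 ng, 31.1% at 10 ng and 6.76% at 1 ng. Its log2 odds rose by 2.30 per unit of log10 input (SE 0.13, limma adjusted p = 0.00197). The windows before it on chromosome 3, starting at 133140000 and 133130000, rose by 1.99 and 2.08 on the same scale, and were at 8.26% and 6.65% at 1 ng. The window of chromosome 10 from 62290000 to 62299999 rose by 2.03, from 5.98% at 1 ng to 56.4% and 66.6% in the 200 ng replicates, and that of chromosome 14 from 19530000 to 19539999 rose by 1.64, from 16.3% to 75.9% and 72.6%. Each of the 14 windows held a larger share of the reads at 1 ng than at 200 ng, by a median of 3.50 times. The windows named on chromosomes 3 and 10 held 9.27 to 13.7 times the 200 ng share. They are among the windows with an excess of reads at 1 ng described under other observations. That excess lay in clusters of CpGs with a low level at 1 ng, picked by their 1 ng reads. In the chromosome 10 region the CpGs outside the clusters were at 69.2% at 1 ng and 69.9% in the pooled 200 ng libraries. The rise there thus does not show a change of methylation across the region. In the chromosome 3 region the CpGs outside were also lower at 1 ng, at 56.5% against 77.7%, so for these windows this stays open. The count depended on single libraries: 0 windows rose without the 1 ng library, 2 without the 50 ng library, 15752 without the 10 ng library, 4 without 200 ng replicate 1 and 2 without replicate 2. It was 793 with windows weighted by counting error and 2 with each library centred on its median window. Windows that fell numbered 7 in the weighted fit and 1363 without the 10 ng library. Windows of 100 kb gave 8862 rises and 6 falls.

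**Figure D2:**
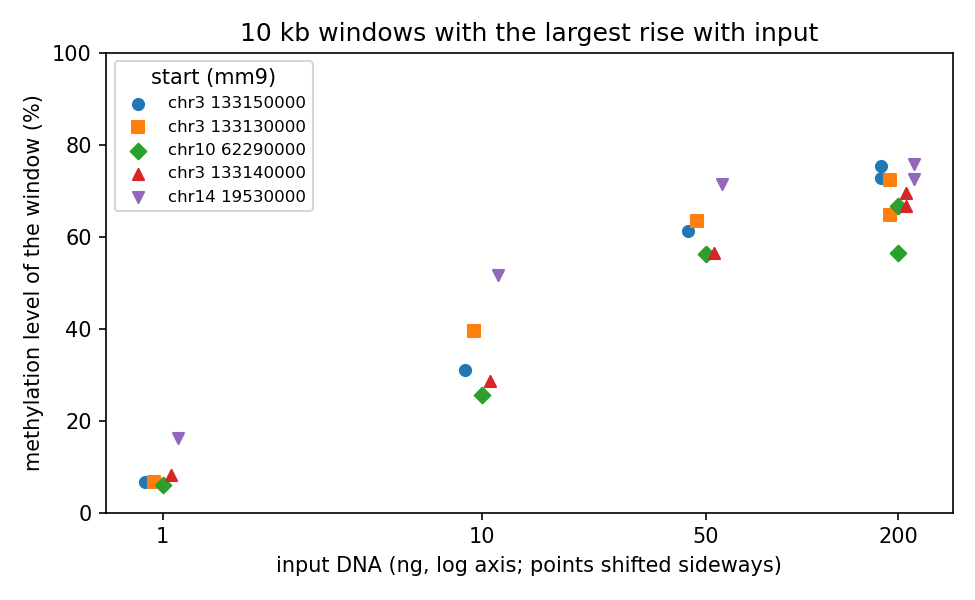
Methylation level in percent (vertical axis) of the 5 windows of 10 kb with the largest rise with input, against the input in ng on a log axis (horizontal axis); each marker is 1 library, with 2 at 200 ng, and markers are shifted sideways so that they can be told apart. The levels at 1 ng lie between 5.98% and 16.3%, and those at 200 ng between 56.4% and 75.9%. The windows of chromosomes 3 and 10 held an excess of reads at 1 ng.

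The enrichment method was compared with rrTAPS at the same CpGs. At 708251 CpGs the mean level was 35.9% in the pooled 200 ng libraries and 38.4% in rrTAPS, and levels correlated with r = 0.654. CpGs with few neighbours were higher in eeTAPS and CpGs with 10 to 19 neighbours lower. In the pooled libraries the difference was 26.4 points with 0 to 1 neighbours, 11.2 with 2 to 4, -1.88 with 5 to 9, -8.89 with 10 to 19, -0.947 with 20 to 39 and 1.82 with 40 or more. With 10 to 19 neighbours eeTAPS was lower in each of the 5 libraries, with differences of -7.82 and -5.43 points in the 200 ng replicates, -3.93 at 50 ng, -2.42 at 10 ng and -7.61 at 1 ng, and also in each at a coverage of 1. At a coverage of 10 the pooled libraries (-7.88), replicate 1 (-5.55) and the 1 ng library (-4.20) were lower, while the intervals across CpGs of replicate 2 (0.419), 50 ng (0.106) and 10 ng (0.401) included 0. Of CpGs at 80% or more in rrTAPS, 84.1% and 85.3% were at 50% or more in the 200 ng replicates, 89.9% at 50 ng, 89.3% at 10 ng and 80.9% at 1 ng. At a coverage of 10 the order changed, to 91.8% and 94.2%, 87.7%, 79.7% and 71.7%, the last from 113 CpGs. Of CpGs below 5% in rrTAPS, between 90.9% and 97.4% were below 50% in an eeTAPS library, and between 89.3% and 98.4% at a coverage of 10. With 5 reads, the 50 and 10 ng libraries measured only 2897 and 2195 of 488010 such CpGs. Fisher's exact test called 22866 CpGs, or 3.23%, with eeTAPS higher at 11999 and lower at 10867, and 64.7% of CpGs lay within 20 points. This split moved with the coverage minimum, to 9277 higher and 5966 lower at 3, 10512 and 10973 at 10, and 6061 and 3555 at 20. With either 200 ng replicate alone, eeTAPS was more often higher than lower at the called CpGs. The mean difference, -2.47 points, changed sign with the coverage minimum (7.96 at 1, 0.745 at 3, 2.69 at 20) and without 200 ng replicate 1 (0.468), and was -1.55 without replicate 2. The share called was 2.00% without replicate 1 and 1.91% without replicate 2.

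**Figure D3:**
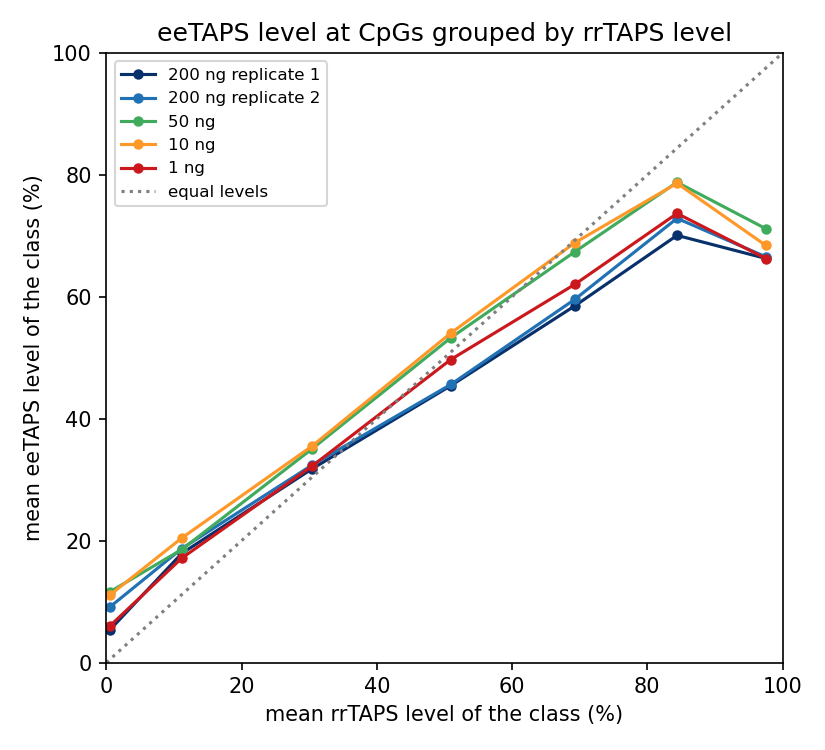
Mean eeTAPS level in percent (vertical axis) of CpGs grouped by their rrTAPS level, against the mean rrTAPS level of the group in percent (horizontal axis), for CpGs with 20 reads in rrTAPS and 5 in the eeTAPS library; each line is 1 eeTAPS library and the dotted line marks equal levels. In 200 ng replicate 1 the groups rise from 5.42% to 70.1% where rrTAPS rises from 0.556% to 84.4%, and fall to 66.3% in the group at 97.5%.

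The X chromosome was compared with the autosomes within each library. Its level was 74.9% and 75.9% in the 200 ng replicates, above the autosome medians by 5.19 and 5.68 points and above each of the 19 autosomes. The rrTAPS level of X, 28.5%, was 2.70 points above the autosome median and likewise ranked highest. An exact rank among 20 chromosomes allows no p below 0.05, which is the value for these 3 libraries. In the 50, 10 and 1 ng libraries X ranked 9, 13 and 13 from the highest, with differences of 0.270, -1.44 and -0.415 points. At a coverage of 1, X ranked highest in each eeTAPS library, 4.69 to 5.81 points above the autosome median. At a coverage of 10 it ranked 8 in 200 ng replicate 2 (1.06 points above the median), 16 at 50 ng (-12.1), 15 at 10 ng (-10.9) and 11 at 1 ng (-5.69), while it stayed highest in replicate 1 and rrTAPS. In rrTAPS it ranked 14 (-1.07 points) by unweighted means at a coverage of 1. In single density classes of 200 ng replicate 1, X was higher by 2.03 to 5.68 points, and in those of replicate 2 the difference ran from -0.211 to 8.70 points. In the sparsest class X was lower at 50 ng (-1.85), 10 ng (-5.06), 1 ng (-5.59) and in rrTAPS (-7.56).

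**Figure D4:**
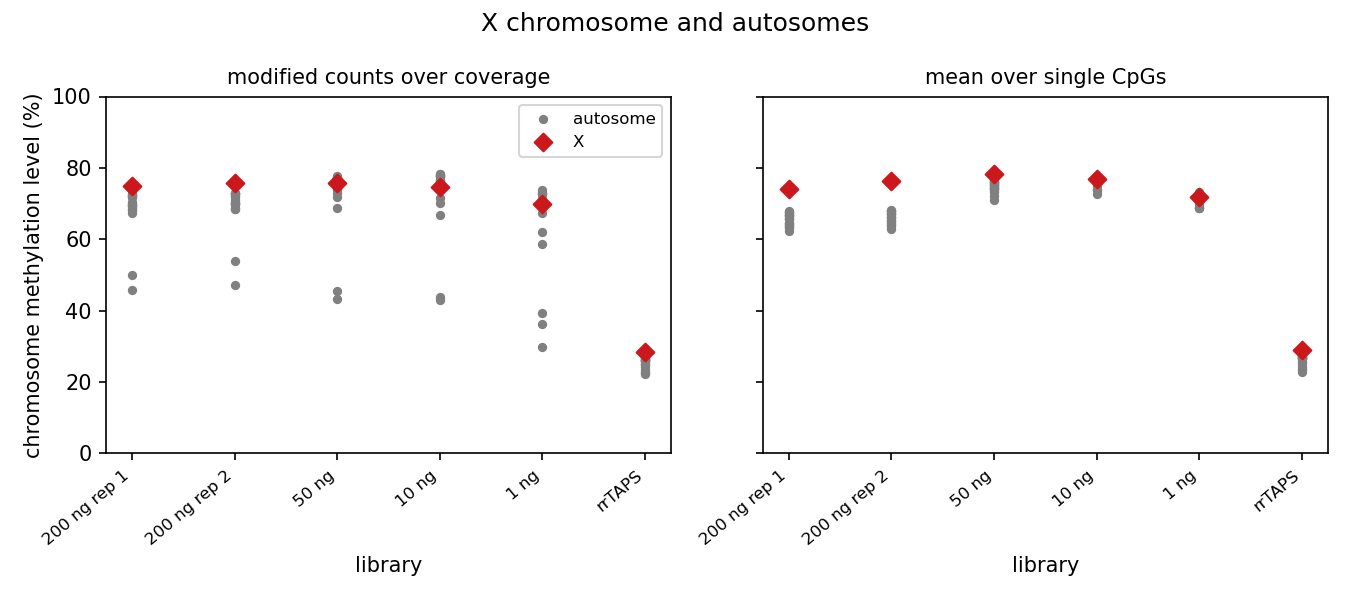
Methylation level in percent (vertical axis) of the X chromosome (red diamonds) and the 19 autosomes (grey points) in each library (horizontal axis), as modified counts over coverage (left) and as means over single CpGs (right), at a coverage of 5. X lies above each autosome in both 200 ng libraries and rrTAPS in both panels. The lowest autosome of an eeTAPS library in the left panel is chromosome 10 of the 1 ng library, at 29.9%. It holds the window from 62270000 to 62279999 with an excess of reads, and is at 71.7% in the right panel.

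CpG-dense stretches had low levels, as in the densest classes of single CpGs. Of 22341 stretches, 13380 were measured in the pooled 200 ng libraries, with a median of 10.9%, and 15134 in rrTAPS, with a median of 0.460%. A level of 50% or more was found in 241 (1.80%, 95% interval 1.58 to 2.04%) and 237 (1.57%, 1.37 to 1.78%) of these. Replicates 1 and 2 gave 1.59% and 0.401% when taken alone. Both 200 ng libraries were at 50% or more in 9 of the 3006 stretches measured in each. The longest methylated stretches of the pooled libraries, by number of CpGs, were X 26565821 to 26567689 with 90 CpGs at 60.2% (95% interval 50.1 to 69.7%) and X 18298507 to 18299883 with 86 CpGs at 53.3% (46.6 to 59.9%). They were followed by stretches on chromosome 18, 64208350 to 64209674, at 65.4% (61.2 to 69.5%), chromosome 7, 4143877 to 4144926, at 69.2% (65.3 to 72.9%), and chromosome 8, 50158076 to 50159304, at 52.1% (46.4 to 57.7%). In this order, the 5 stretches were measured at only 10, 15, 29, 25 and 21 of their CpGs, those with a coverage of 5. The levels of their other CpGs are not known. Only those on chromosomes 18 and 7 were measured in a single replicate, at 67.6% and 75.4% in replicate 1, and none of the 5 was measured in rrTAPS. Of 161 stretches at 50% or more in rrTAPS that eeTAPS measured, 18 were at 50% or more in the pooled libraries, 127 at 25% or more and 0 below 10%. Across the 8981 stretches measured by both methods, r was 0.720.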

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

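No statistical test was run on the values in this part, and their use in weighing the level at 1 ng was chosen after they were seen. Uncleaved modified reads entered the comparisons of levels only in sum with the cleaved ones, and their share was set apart because it lay above the limit that a count of 0 allows, with the untreated control not analysed here. Of modified reads at CpGs with at most 500 reads in the library, 11.6% were uncleaved in 200 ng replicate 1, 6.35% in replicate 2, 7.42% at 50 ng, 7.61% at 10 ng and 7.37% at 1 ng. With no upper limit on coverage the shares were 15.4%, 7.50%, 9.87%, 9.96% and 8.89%. CpGs with 0 to 1 neighbours had shares of 2.14% to 3.67% and CpGs with 10 to 19 neighbours shares of 14.4% to 24.2%, in each library higher than in the sparsest class. The class of 40 or more neighbours had 39.1% at 1 ng and 13.0% to 19.4% in the other 4 libraries. No explanation of these shares was tested.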

How the results depend on the processing

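Alternatives were computed for 34 results. Of 191 values, 35 kept within the spread or, for counts, within 1.5 times, 143 moved by more and 13 changed sign. The cause was not tested where none is given. For the genome level of a single library the spread covered counting error only, which is very narrow. At 50 ng the interval ran from 63.28% to 63.31%, so autosomes alone, at 63.21%, counted as moved. Across windows of the 200 ng replicates, rho of 0.912 against r of 0.910 also counted as moved. The number that moved thus does not show how large the changes were. The fits without the 50 or 10 ng library, centred on the median window or weighted by counting error, and levels without windows of 100 times the median coverage, were chosen after the result was seen, as were the comparison at thinned depth and the test without windows of over 3 times the share of reads at 1 ng, which left that difference at -5.03 points. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers. Promoter alternatives were not run, since no gene was placed in mm9. Depth limited calls of single CpGs: at the real coverage 27% of simulated changes of 80 points were recovered at 1 ng, and that simulation held no changed CpG with 20 reads in both libraries.

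Levels in the order 50, 10, 1 ng and rrTAPS were 61.8%, 61.9%, 57.0% and 27.0% at a coverage of 1, 63.5%, 63.4%, 57.7% and 25.6% at 3, 52.5%, 47.0%, 36.6% and 25.06% at 10, and 41.1%, 41.1%, 30.7% and 25.1% at 20. Unweighted means were 74.7%, 76.0%, 71.1% and 26.0%, autosomes alone gave 63.2%, 61.3%, 54.0% and 25.08%, and the 9932 CpGs covered in all 6 libraries gave 39.5%, 40.3%, 33.5% and 35.0%, with 39.8% at 200 ng. Without windows of 100 times the median coverage, levels were 70.9% at 200 ng and 75.9%, 76.6%, 71.1% and 25.14% in the others. The 200 ng level kept within its SD under the other settings. Without replicate 1 or 2 it was 66.5% or 62.9%, but 1 of 2 replicates always lies within the SD of their mean.

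Between the 200 ng libraries, r across CpGs was 0.620, 0.689, 0.782 and 0.838 at a coverage of 1, 3, 10 and 20, and Spearman's rho 0.685. The share called was 0.00148%, 0.00845% and 0.0531% at 1, 10 and 20. Across windows rho was 0.912, and r 0.871 at 1 kb and 0.968 at 100 kb.

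Against pooled 200 ng, differences at 50, 10 and 1 ng were -1.29, -0.716 and -4.66 points at a coverage of 1, -0.387, 0.345 and -3.75 at 3, and 0.874, 1.5 and -2.02 at 10. The values of r were 0.579, 0.544 and 0.516 at 1, 0.685, 0.649 and 0.596 at 3, and 0.824, 0.849 and 0.825 at 10. Shares called were 2.585e-04%, 3.910e-04% and 0.00262% at 1, 5.618e-04%, 0.00117% and 0.0177% at 3, and 0.0172%, 0.106% and 1.26% at 10. Without a 200 ng replicate, differences ranged from -0.409 to 1.87 points at 50 ng, 0.240 to 2.64 at 10 ng and -3.62 to -1.46 at 1 ng, r from 0.690 to 0.691, 0.656 to 0.662 and 0.604 to 0.605, and shares from 0.00189% to 0.00256%, 0.00473% to 0.00754% and 0.0217% to 0.0755%.

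For eeTAPS less rrTAPS, differences at a coverage of 1, 3, 10 and 20 were 7.96, 0.745, -3.06 and 2.69 points, r 0.331, 0.580, 0.660 and 0.671, and shares called 0.0867%, 0.8995%, 8.29% and 14.8%. Without a replicate they ranged from -1.55 to 0.468 points, 0.551 to 0.614 and 1.91% to 2.00%. Other thresholds gave 2.68% to 3.27%.

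The sparsest density class was at 76.2% and 51.6% (200 ng and rrTAPS) with a radius of 100 bp and at 90.2% and 46.7% with 500 bp, and at 84.7% (200 ng) with a coverage of 1 and 89.7% with 10. The densest was at 13.6% (200 ng) and 2.5% (rrTAPS) with 500 bp, and in rrTAPS at 0.317% with 100 bp and 0.696% with a coverage of 1. X less the autosome median, for 200, 50, 10 and 1 ng and rrTAPS, was 9.16, 3.11, 0.802, 0.219 and 2.28 points unweighted, 4.87, 5.32, 5.59, 5.81 and 2.40 at a coverage of 1, and 2.27, -12.1, -10.9, -5.69 and 2.79 at 10. Stretches at 50% or more were 0.585% (pooled 200 ng) and 0.306% (rrTAPS) with gaps of 40 bp, and 0.154% and 0.221% with at least 60 CpGs. By construction, 13.3% and 5.23% were at 25% or more and 0.0523% and 0.172% at 75% or more. Without a replicate the pooled share ranged from 0.401% to 1.59%.

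Windows that rose with input numbered 8862 with 100 kb windows, 22 with an offset of 2, 532 with a coverage of 200, 13813 for 1 ng against the other 4 libraries, 2 when centred, 793 when weighted, 2 without the 50 ng, 15752 without the 10 ng and 0 without the 1 ng library, and 2 to 4 without a replicate. Falls numbered 6 with 100 kb windows, 2 with a coverage of 200, 1506 for 1 ng against the others, 7 when weighted, 1363 without the 10 ng library and 0 without either replicate.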

Other observations

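The tests of the choice of windows, of reads from uncut DNA, of lower conversion, of stretches on X and of the windows with an excess of reads were chosen after the result was seen, and the bounds of the tests of the excess, of the choice of windows and of uncut DNA were set with their values known. Regions with little methylation stood out in the pooled 200 ng libraries: 516 runs of at least 3 kb and 35 of at least 5 kb had each 1 kb window of at least 20 reads below 10%, a definition chosen after the data were seen. The longest outside the mitochondrial genome, chromosome 5, 123585000 to 123592999, was at 3.02% in the pooled 200 ng libraries and 0.366% in rrTAPS, and that of chromosome 9, 56919000 to 56925999, at 3.81% and 0.297%. Of the CpG-dense stretches at 50% or more in both methods, the longest by number of CpGs, chosen after the data were seen, were chromosome 1, 114340537 to 114341240, at 61.9% in the pooled libraries and 51.6% in rrTAPS, and chromosome 18, 7318618 to 7319375, at 53.1% and 64.4%. Each held 47 CpGs, of which 10 and 24 were covered in the pooled libraries and 23 and 16 in rrTAPS. On X, 3.63% of the stretches of rrTAPS were at 50% or more against 1.504% elsewhere (Fisher's exact p = 0.00247, two-sided), and in the pooled 200 ng libraries 2.73% against 1.77% (p = 0.142). The shares were 3.77% against 1.52% in 200 ng replicate 1 (Fisher's exact p = 0.0135) and 0.654% against 0.391% in replicate 2 (Fisher's exact p = 0.465). These tests took stretches as independent, but X is a single chromosome. Their p-values therefore do not measure a spread between chromosomes or between samples.

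Among 134792 windows of 10 kb at 40% or more in rrTAPS, 12 had a share of the reads at 1 ng of at least 5 times that of the pooled 200 ng libraries. The median over the 255547 windows with at least 100 pooled reads, whatever their rrTAPS level, was 0.966. The window of chromosome 10 from 62270000 to 62279999 held 1.74% of all coverage at 1 ng against 0.0248% in 200 ng replicate 1, and its level was low in each eeTAPS library, at 3.43% and 3.91% in the 200 ng replicates, 3.52% at 50 ng, 2.88% at 10 ng and 2.44% at 1 ng, against 58.3% in rrTAPS. Single CpGs counted as having an excess with a coverage of at least 20 at 1 ng and at least 5 times the pooled share. The 1 ng reads thus made this split, and the contrast in 1 ng level may in part be built in. In chromosome 10 from 62270000 to 62299999 the excess lay in 5 clusters with 73 of the 321 CpGs, at 2.36% at 1 ng and 2.55% in the pooled 200 ng libraries. The other 248 CpGs were at 69.2% at 1 ng (95% interval 64.5 to 73.5%) and at 69.9% in the pooled libraries. In chromosome 3 from 133130000 to 133159999 it lay in 94 of 250 CpGs, at 2.80% at 1 ng and 51.6% in the pooled libraries, with the others at 56.5% (51.9 to 61.1%) against 77.7%.

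For this excess, amplification of a few molecules by chance needs the 10 and 50 ng libraries to be unordered, but 10 ng exceeded 50 ng in 100% of the windows, and extra copies in the cells need equal shares in all libraries, but the median 10 ng share was 1.75 times that of 200 ng. That test replaced the lowest 1 ng share, which the choice of windows fixes. A fixed amount of unmodified DNA of these sequences, added to each reaction of 50 ng or less, stays open. The 50 ng share exceeded that of 200 ng in 41.7% of the windows, and the 200 ng replicates themselves differed from their pool by up to 1.37 times. In 200 ng replicate 1 the chromosome 10 window starting at 62270000 held a coverage of 70885, against 1809 in that starting at 62290000. The 200 ng baseline may itself hold an excess there, so the 50 ng share cannot decide for that window. Whether the 200 ng reactions held the same amount as the 50 ng reaction is open too. The 50 ng share was 1.30 times that of 200 ng, where the same amount in 4 times less input would raise it about 4 times. That median rests on 2 adjoining windows, however, and the labels give no amounts of reagents. Apart from extra copies in the cells, no biological explanation was tested, since all libraries came from the same cell line. The rrTAPS adapters were ligated before conversion, so that DNA added with the reagents would have had no adapters.

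The lower level of 10 kb windows at 1 ng is not accounted for by the choice of windows by their coverage at lower depth: over 25675 windows of 100 kb the difference was -5.50 points. Reads from DNA that was not cut at modified CpGs stay open: the relative coverage of CpGs below 5% in rrTAPS was 1.84 times that of the highest of the other 4 eeTAPS libraries. The uncleaved share of modified reads was not raised over all CpGs, at 7.37% against 6.35% to 11.6%, and stood apart only at CpGs with 40 or more neighbours (39.1% against 13.0% to 19.4%). A lower conversion of modified CpGs alone cannot be told apart from this: that coverage was 1.86 times that at 10 ng, more than the fall of the level, but how coverage responds to fewer cuts after size selection is not known. No biological explanation was tested, and with 1 library at 1 ng the effect of PCR cycles stays open.

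Patterns set aside after they were weighed are given as values. For the eeTAPS level, higher than that of rrTAPS at sparse CpGs and lower at CpGs with 10 to 19 neighbours, no test here separated size selection or GC content from local density. Of the difference between X and the autosomes in unweighted levels, 8.50 and 10.2 points in the 200 ng replicates, 3.04 and 3.74 points were left when density classes were weighted as on X, and 1.13, -0.628 and -1.48 points at 50, 10 and 1 ng; at a coverage of 1, 1.33 to 2.14 points were left in the 5 eeTAPS libraries. In rrTAPS 3.03 points were left at a coverage of 5 and -0.0123 at 1. The unweighted level at a coverage of 5 was above that of 200 ng replicate 1 by 8.91, 10.2 and 5.30 points at 50, 10 and 1 ng. Replicate 1 thinned to the same depths rose by 8.97, 10.9 and 12.5 points, and a median of 100.3% of the rise was left without CpGs of more than 500 pooled reads.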
